A study of Mus musculus with 3 samples.

How the data were processed

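CUT&Tag was run on the lateral ganglionic eminence of wild-type CD1 mouse embryos at E14.5, with 2 MEIS2 libraries and 1 library without a primary antibody, from 100000 cells each and paired-end reads of 150 bp, per the labels. The samples were grouped by those labels. Each library has 1 peak table. Per the file headers, peaks were called in each library on its own with MACS 2.2.7.1, with no control file, a q cutoff of 0.05, at most 1 tag kept per position, and the BAM format setting that does not use read pairs. The submitters' processing notes name Trimmomatic, Picard, Bowtie2 2.3.4, MACS2 2.1.4 and mm10, so the 2 sources give different MACS versions. The order of these steps is not given in the sources used here. The BAM names in the headers carry a mark for removed duplicates, yet the headers also give a redundant rate of 0.90, 0.92 and 0.91, and the caller kept 7618406 of 74259592 tags in MEIS2 replicate 1, 6559629 of 79760948 in replicate 2 and 6337375 of 72763762 in the no-antibody library. Intervals given for shares cover counting error only.

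The deposited signal is the pileup, the number of extended tags stacked at the summit, and it is not scaled to depth. The deposited fold enrichment is a ratio, the pileup plus 1 over the locally expected pileup plus 1. The deposited −log10 p-value and −log10 q-value columns are MACS's, within each library. The deposited positions and lengths were used as given, 1-based. Fold enrichment was compared between libraries by rank or overlap, and pileup only by rank or as a median. Because the caller had no control, a MEIS2 peak here is a local excess of tags, and the no-antibody list was set against it by overlap. The control lacks the antibody, so it does not measure off-target binding of an antibody.

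Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, with 49943 placed genes, 21887 of them protein-coding. The table gives start, end and biotype without strand, exons or transcription start sites. The results on promoters, meant to be within 1 kb of a transcription start site, were therefore computed as summits within 1 kb of either end of a gene. Distal peaks were summits more than 1 kb from every gene end, counted in each gene and 50 kb around it per 100 kb of that window. For genes longer than 100 kb, only the 50 kb on either side of each end were counted, so the middle of such genes was left out. Exons, introns and UTRs were not told apart. The 2 planned results on the MEIS motif need a genome sequence and were not run. Peaks on sequences other than chromosomes 1 to 19, X and Y (315, 323 and 69) were left out of the main results.

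Overlap meant at least 1 bp. Overlap shares and gene-end shares were set against 1000 circular shifts of the peaks along each chromosome, which keep widths and spacing, with one-sided permutation p-values. Gene-end shares of 2 peak sets were compared with Fisher's exact test, two-sided, over peaks, which are not biological replicates. The 20 gene lists were LGE regulators, D1 and D2 striatal projection neuron markers, spiny neuron and GABA markers, radial glia and progenitors, MGE and interneurons, dorsal cortical excitatory neurons, dorsal LGE and olfactory bulb, oligodendrocyte lineage, vessels and microglia, TALE homeobox, retinoic acid, Notch pathway, axon guidance, GABA and dopamine synapses, Hox clusters, ribosomal proteins, olfactory receptors, keratins, and liver, muscle and pancreas. Every listed symbol was found in the table, and only protein-coding members were counted. Some genes are in more than 1 list. Each list was compared with the other protein-coding genes by Fisher's exact test and, for distal peaks, with 10000 random protein-coding lists of its size, one-sided, each with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. The tests treat genes as independent, which clustered genes are not. No test compares MEIS2 with the control across libraries, since the control is 1 library.

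The lists, the tests, the other settings to try and the rule for named genes were fixed before the data were examined, apart from the gene-end and distal definitions given above. The plan for distal peaks was the mean number per gene within 50 kb of its transcription start site, not scaled to window length. The rule named Meis2, Dlx1, Dlx2, Six3 and Zfp503; from each list up to 4 genes with the strongest gene-end peak by the lower fold enrichment of the replicates, up to 4 with the most distal peaks and up to 2 without any, in alphabetical order; the 10 reproducible peaks with the highest lower fold enrichment; and the 5 no-antibody peaks with the highest fold enrichment. Names are given for the lists where they matter most. Dlx5 and Gsx2 and the positions at Dlx6, Drd1, Drd2 and Isl1 were chosen after their values were seen. The alternatives were 50% reciprocal overlap, −log10 q of at least 5, the 5000 peaks of highest fold enrichment in each list, all sequences, each MEIS2 replicate left out, replicate 2 as the base list, peaks with a no-antibody overlap kept in, gene-end distances of 500 and 2500 bp, ends of protein-coding genes, a background of genes with a gene-end peak in any library, windows of 100 kb, and random lists matched on a gene-end MEIS2 peak. Random lists matched on gene length, on local gene density, or drawn as runs of neighbouring genes were added after the data were seen. Alternatives to overlap shares used 200 shifts. The gene-end distance of 500 bp was used for the share of peaks at gene ends and not for the gene lists.

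The steps were tested on simulated data. A simulated list with 60% of its peaks taken from replicate 2 gave an overlap of 60.8%, and a simulated gene-end share of 25% came back as 25%. For simulated lists of 20 genes in the gene-end comparison, the test called 95.5% of lists with a share of 90%, 91% of lists with a share of 10% and 20.5% of lists with a share of 70%, against a base of 50%, and 0.5% of unchanged lists. For distal peaks it called 99% of simulated lists of 20 genes with doubled density and 1.33% of unchanged lists. Genes were drawn at random with densities shuffled over genes, so these rates do not hold for clustered lists such as the Hox genes. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.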

Results

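MEIS2 is a homeodomain transcription factor of the TALE class. Its binding in the embryonic mouse forebrain was profiled by CUT&Tag, in which an antibody tethers the Tn5 transposase so that DNA near the bound protein is cut and tagged. The tissue was the lateral ganglionic eminence (LGE), the progenitor region of striatal projection neurons, of wild-type CD1 embryos at E14.5. There were 2 MEIS2 libraries, used as replicates, and 1 library made without a primary antibody, each from 100000 cells. The files list peaks called in each library separately. After removal of repeated positions the peak caller used 7618406 tags in MEIS2 replicate 1, 6559629 in replicate 2 and 6337375 in the no-antibody library. On chromosomes 1 to 19, X and Y these gave 78060, 82093 and 9869 peaks, which covered 31.2, 28.3 and 3.63 Mb. The study's title names Dlx1, Dlx2 and Meis2 in the striatum, and the comparisons below ask where MEIS2 peaks lie, how far they repeat, and which genes carry them. A reproducible peak is a replicate 1 peak that overlaps a replicate 2 peak by at least 1 bp and no no-antibody peak. Fold values are the caller's fold enrichment of replicate 1 and then of replicate 2. All positions are mm10.

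Dlx1 and Dlx2 both carried reproducible MEIS2 peaks. The Dlx1 peak lay inside the gene at 2:71528896-71529719, with fold enrichments of 5.33 and 5.36 and a summit 1377 bp from the nearer gene end. Dlx2 had 2 peaks within 1 kb of one end, at 2:71545873-71546459 (5.11 and 3.71) and 2:71546687-71546901 (3.64 and 3.16). Between the 2 genes lay further peaks at 2:71538722-71538964 (5.15 and 3.36) and 2:71541327-71541554 (4.00 and 3.33). On the far side of Dlx2, the peaks of highest fold enrichment at the locus lay at 2:71564427-71564622 (8.82 and 6.38) and 2:71581095-71581299 (7.06 and 6.32). Their replicate 1 pileups of 14 and 11 were the lowest there, against 21 inside Dlx1 and 28 and 17 at the end of Dlx2. For comparison, the replicate 1 medians of reproducible peaks were 7.26 for fold enrichment and 17 for pileup. Dlx5 and Dlx6 had a peak at an end of Dlx6 (6:6863416-6864189, 7.1 and 7.28), one at an end of Dlx5 (6:6881338-6881751, 6.45 and 5.06) and one between them (6:6874507-6875018, 5.21 and 7.40). Meis2 itself, 206 kb long, had 2 peaks inside the gene and none within 1 kb of an end. A further peak lay outside it at 2:115852709-115852999 (7.64 and 5.74). Of the 2 inside, the one with the higher fold enrichment was at 2:115876991-115877273 (10.5 and 14.9). The other, at 2:116064494-116064669 (4.82 and 4.97), had its summit 2944 bp from the gene's higher-coordinate end. Both had a replicate 1 pileup of 20. Six3 held 2 internal peaks, at 17:85618014-85618497 (4.54 and 4.85) and 17:85623565-85623839 (4.91 and 4.52), and another lay outside it at 17:85608322-85609221 (6.08 and 5.04). Zfp503 held 1, at 14:21987331-21987911 (3.52 and 4.49). No no-antibody peak lay within 50 kb of any of these 7 genes.

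**Figure D1:**
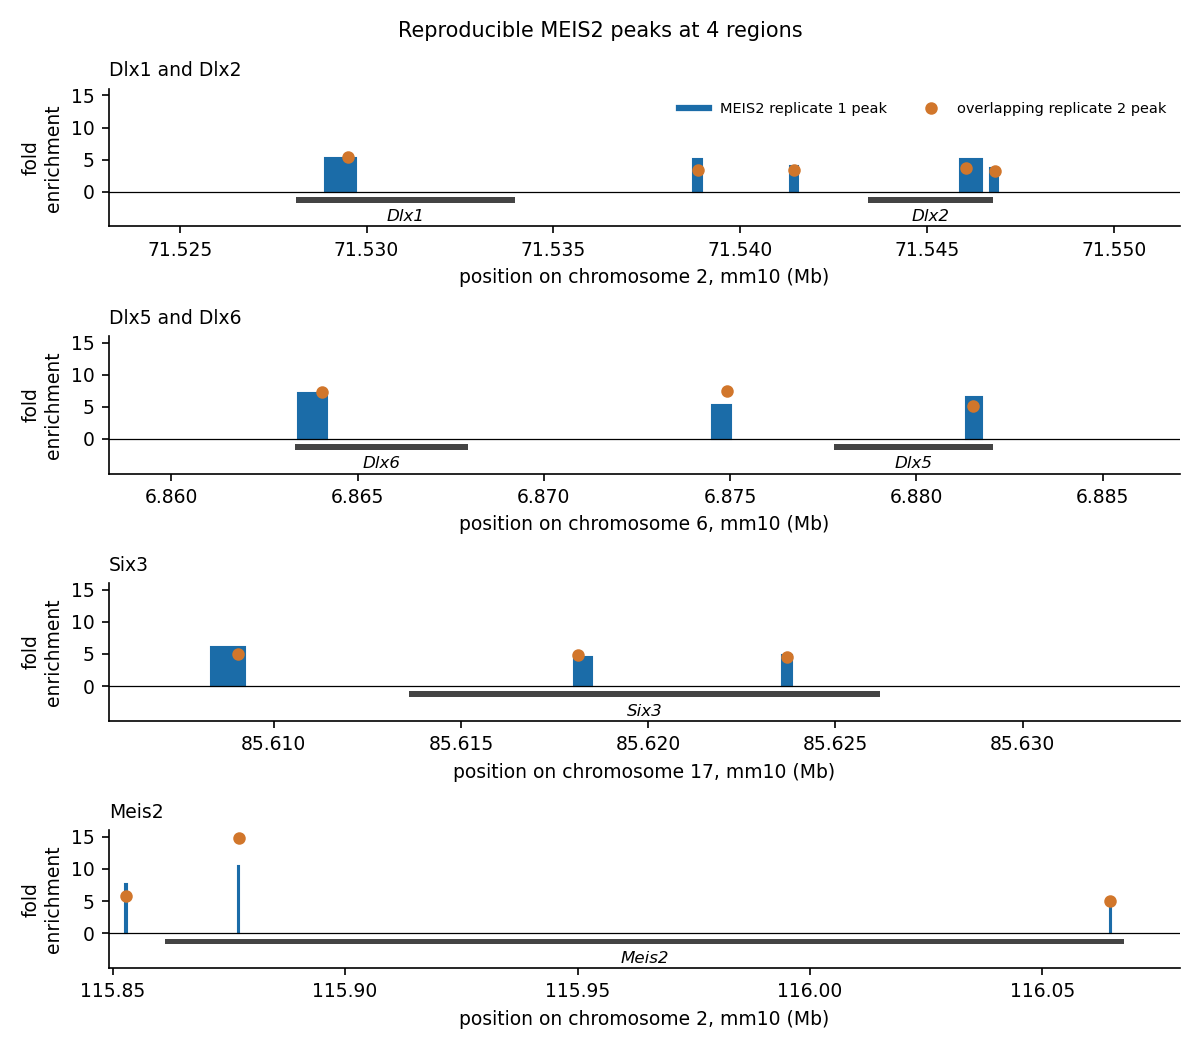
Reproducible MEIS2 peaks at Dlx1 and Dlx2, Dlx5 and Dlx6, Six3, and Meis2, by mm10 position in Mb; bars span the replicate 1 peak and reach its fold enrichment, orange points give the overlapping replicate 2 peak, and dark bars are the annotated genes. The highest value is 14.9, in replicate 2, inside Meis2.

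The reproducible peaks with the highest fold enrichment lay away from the ends of protein-coding genes. The first of the reproducible set lay at 8:39366906-39367301 (25.4 and 26.4), 176 kb from the nearest protein-coding gene, Msr1. Others lay inside Samd5 (10:9581298-9581660, 24.8 and 28.1), Esr1 (10:4730198-4730585, 27.1 and 24.7), Alk (17:72464862-72465291, 24.7 and 26.7) and Jak1 (4:101235030-101235348, 24.3 and 26.3). The rest of the top 10 were 3:33970038-33970446, 49.8 kb from Fxr1, Y:47489346-47489792, 12:10949796-10950146, 140.2 kb from Kcns3, 8:60397909-60398577, 108 kb from Aadat, and 3:17383586-17383914, 565 kb from Cypt12. None of the 10 had its summit within 1 kb of a protein-coding gene end, and the closest to one was the Jak1 peak, 30087 bp away. Of all replicate 1 peaks, 52281 of 78060 (67.0%) overlapped a replicate 2 peak, and 53081 of 82093 replicate 2 peaks (64.7%) overlapped a replicate 1 peak. Circular shifts of one list along each chromosome gave means of 2.29% and 2.19% (one-sided permutation p = 0.001 for both, the smallest that 1000 shifts can give). Strong peaks repeated more often than weak ones. Among replicate 1 peaks clear of no-antibody peaks, 34.0% of the decile with the lowest fold enrichment had a replicate 2 partner, and 99.4% of the highest decile did. In replicate 2 the share was 43.8% in the lowest decile and 96.4% in the highest, without a steady rise between them: it was 37.6% in the fourth. Fold enrichments of shared peaks had a Spearman correlation of 0.756 between replicates, across peaks, which are not independent replicates. The reproducible set held 47809 peaks, and 25560 replicate 1 peaks overlapped neither a replicate 2 nor a no-antibody peak, with a median fold enrichment of 5.13. Each MEIS2 library alone, clear of no-antibody peaks, would give 73369 (replicate 1) or 76287 (replicate 2) peaks.

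The strongest peaks of all were shared with the library made without an antibody. A peak inside Chl1, at 6:103649031-103649379, ranked first in both MEIS2 libraries (41.9 and 42.4), and the no-antibody library had its own first-ranked peak there, at 6:103648975-103649428 (31.8). The next no-antibody peaks were 12:3109743-3110215 (30.0), 1:195371625-195372073 (29.4), 19:61331181-61331649 (28.3) and X:170758108-170758598 (28.0), and all 5 overlapped a peak of both MEIS2 libraries. Of the 10 MEIS2 peaks with the highest fold enrichment in both replicates, 10 overlapped a no-antibody peak. Over the whole lists, 48.4% of no-antibody peaks overlapped a replicate 1 peak and 59.5% a replicate 2 peak, against 2.17% and 2.14% after shifting (one-sided permutation p = 0.001 for both). Seen from the MEIS2 side, 6.01% of replicate 1 and 7.07% of replicate 2 peaks overlapped a no-antibody peak. That share was 25.1% in the decile of replicate 1 peaks with the highest fold enrichment and 2.65% in the lowest. The 4472 shared MEIS2 peaks that overlapped a no-antibody peak had a median pileup of 61 tags, against 17 in the reproducible set. With the lists limited to their 5000 peaks of highest fold enrichment, 17.0% and 18.7% of no-antibody peaks overlapped the MEIS2 lists. With 50% reciprocal overlap over the whole lists, 26.2% and 33.4% did, and 3.31% of replicate 1 and 4.01% of replicate 2 peaks overlapped a no-antibody peak. With 1 no-antibody library, the difference between MEIS2 and control has no replicate check on the control side.

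Gene ends were rich in MEIS2 peaks and poor in no-antibody peaks. Drd1 and Drd2, which mark the 2 classes of striatal projection neuron, had MEIS2 peaks with summits 12 and 33 bp from a gene end, at 13:54055032-54055826 (10.0 and 6.19) and 9:49340209-49340955 (7.39 and 6.95). Isl1 (13:116309349-116310179, 7.56 and 6.98) and Gsx2 (5:75075535-75076344, 8.35 and 5.32) had them too. In the reproducible set, 13657 of 47809 peaks (28.6%, 95% Wilson interval 28.2 to 29.0) had their summit within 1 kb of an annotated gene end, 4.56 times the mean over circular shifts. Of MEIS2 peaks that overlapped a no-antibody peak, 136 of 4472 (3.04%, 2.58 to 3.59) did, 0.502 times the shifted mean. The odds ratio between the sets was 12.7 (95% Wald interval 10.7 to 15.1; the two-sided Fisher p was too small for double precision to hold). The second set was selected by overlap with no-antibody peaks, so its share is tied to theirs, and the odds ratio is not independent of it. Replicate 1 had 23.3% of its peaks at gene ends, replicate 2 19.8% and the no-antibody library 2.51% (2.22 to 2.84), which was 0.419 times its shifted mean. Between genes lay 65.1% of no-antibody peaks and 36.6% of reproducible MEIS2 peaks. Gene-end peaks were wider, with a median of 552 bp against 330 bp elsewhere. The share at gene ends was not highest for the strongest peaks. In replicate 1, clear of no-antibody peaks, it was 21.9% in the lowest decile by fold enrichment, 38.3% in the eighth and 12% in the top decile, and in replicate 2 it was 30.0% in the ninth and 9.15% in the top decile. Among the 5000 strongest peaks of each list, the gene-end share was 2.69% of reproducible peaks and 1.75% of those with a no-antibody peak (odds ratio 1.55, two-sided Fisher p = 0.161). The no-antibody list was cut in the same way, so these reproducible peaks can include some that overlap a weaker no-antibody peak. The annotation gives both ends of each gene without strand, so 5′ and 3′ ends were counted together.

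**Figure D2:**
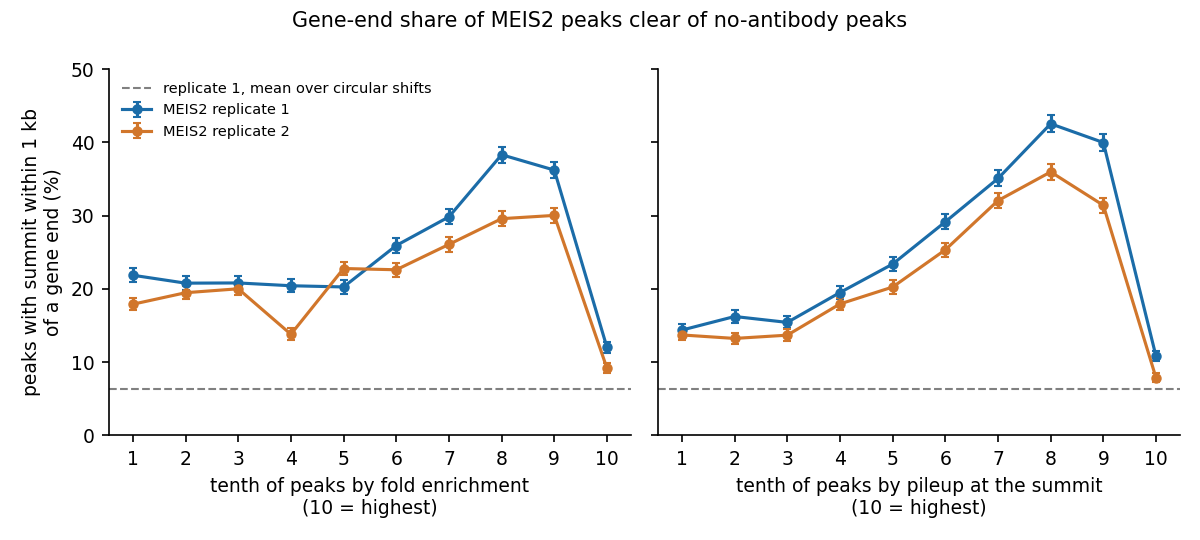
Percent of MEIS2 peaks, clear of no-antibody peaks, with a summit within 1 kb of a gene end, by decile of fold enrichment (left) and of pileup (right), with 95% Wilson intervals; the dashed line is the mean over circular shifts of replicate 1. In both replicates and by both measures the top decile is lowest, between 7.84% and 12%.

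Notch pathway genes carried MEIS2 peaks at their ends in 84.2% of cases, the highest share of 20 gene lists chosen before the data were examined, though not under every setting. Hey2, Heyl, Notch2 and Numb had the strongest of them, with lower-of-replicates fold enrichments of 8.93, 8.93, 8.62 and 8.53, and Dll3 and Hes1 had none. Of 21887 protein-coding genes, 11461 (52.4%) had a reproducible peak within 1 kb of an end, against 59 (0.270%) with a no-antibody peak. The Notch list had 16 of 19 (84.2%, odds ratio 4.86, adjusted p = 0.0261; two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 20 lists, here and for the lists that follow). Leaving out a replicate moved this odds ratio to 6.88 (without replicate 1) or 11.8 (without replicate 2), with adjusted p = 0.0213 and 0.00994 by the exact test. Ribosomal protein genes, which every cell uses, had 54 of 78 (69.2%, odds ratio 2.05, exact test, adjusted p = 0.022), led by Rpl37, Rps25, Rpl14 and Rps23. Olfactory receptor genes had 24 of 1106 (2.17%, odds ratio 0.0181, exact test, the smallest adjusted p of the 20), with an odds ratio of 0.0299 without replicate 1, and genes of liver, muscle and pancreas 3 of 18 (16.7%, odds ratio 0.182, adjusted p = 0.022), namely Actn2, Myh7 and Ahsg. LGE regulators had 18 of 26 (69.2%, Wilson interval 50.0 to 83.5, odds ratio 2.05, exact test, adjusted p = 0.442), led by Foxp2, Tcf12, Dlx6 and Isl1, with Dlx1 and Etv1 among those without. The other striatal lists were 9 of 13 D1 neuron markers (Sfxn1, Isl1, Tac1 and Drd1 strongest, Eya1 and Mef2c without), 7 of 12 D2 neuron markers (Drd2, Ikzf1, Ptprm and Gucy1a1 strongest, Gpr52 and Gpr6 without) and 8 of 16 spiny neuron and GABA markers (Arpp21, Rgs9, Ppp1r1b and Foxp1 strongest, Gad1 and Gad2 without). Neighbouring regions and other lineages gave 10 of 14 medial ganglionic eminence (MGE) and interneuron genes, led by Satb1 (9.30), 7 of 15 dorsal cortical genes, led by Lhx2 (9.06), 7 of 12 genes of the dorsal LGE and olfactory bulb, 12 of 20 of radial glia and progenitors, 5 of 10 of the oligodendrocyte lineage and 5 of 15 of vessels and microglia. Further lists gave 11 of 18 TALE homeobox genes, led by Pbx4 (8.93), 10 of 16 of retinoic acid signalling, 16 of 28 of axon guidance, 7 of 16 of GABA and dopamine synapses, 25 of 39 Hox genes and 21 of 49 keratins. Adjusted p-values of the 16 lists not called ran from 0.442 to 1. In the no-antibody list, 3 olfactory receptor genes and no gene of the other 19 lists had a peak at an end. The calls moved when the distance that counts as an end was raised, and a shorter distance was not run for the lists. At 2.5 kb, by the same exact test, LGE regulators (odds ratio 4.96, adjusted p = 0.0156), MGE and interneuron genes (8.41, 0.042) and Hox genes (4.40, 0.00436) also passed the threshold, while the liver, muscle and pancreas list did not (0.323, 0.0769). Notch and ribosomal protein genes did not pass the exact test with 50% reciprocal overlap (adjusted p = 0.314 and 0.678) or with −log10 q of at least 5 (0.289 and 0.105). Under both of these settings the odds ratios of MGE and interneuron genes (3.01 and 3.70) and of D1 neuron markers (2.71 and 2.37) were above that of the Notch list (2.61 and 2.03). With −log10 q of at least 5, the exact test called keratins (0.288, adjusted p = 0.00389) and vessels and microglia (0.105, 0.0344) lower.

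**Figure D3:**
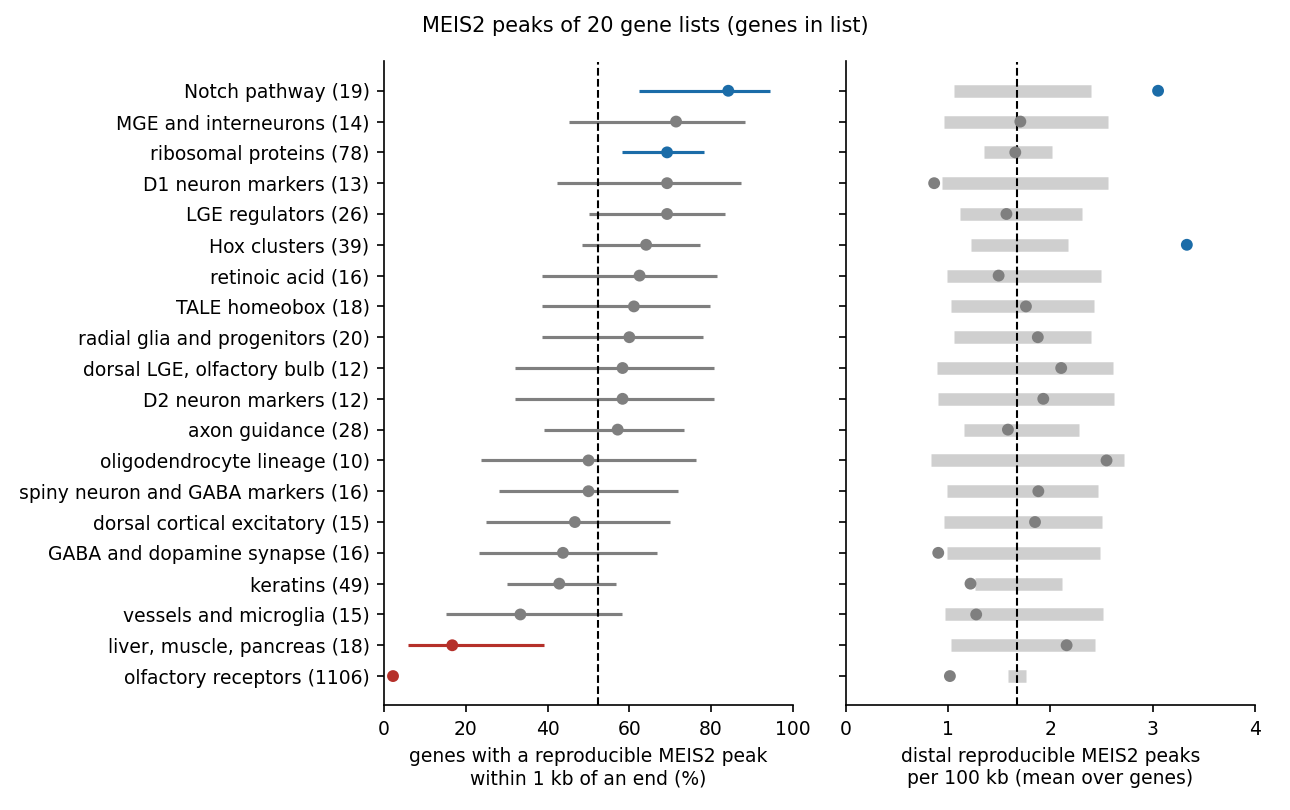
Left, percent of genes of each list with a reproducible MEIS2 peak within 1 kb of an end, with 95% Wilson intervals; right, mean distal reproducible peaks per 100 kb, with grey bars for the central 95% of 10000 random lists. Dashed lines mark all protein-coding genes (52.4% and 1.67), blue marks lists called higher and red lists called lower; the Notch list is called in both panels.

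Distal MEIS2 peaks, away from every gene end, were densest, among the 20 lists, around Hox and Notch pathway genes. Notch3 had 9 such peaks in the gene or within 50 kb, Lfng 7 and Jag2 6, and Numb had 6 within 50 kb of its ends. None of the 19 Notch genes lacked a distal peak. The mean over protein-coding genes was 1.67 distal peaks per 100 kb. Notch genes had 3.05 ± 0.390 (SE over genes), 1.82 times random protein-coding lists (adjusted p = 0.006, one-sided permutation test on 10000 random lists, Benjamini-Hochberg over the 20 lists). Hox genes had 3.34, 1.99 times random (permutation test, adjusted p = 0.002), but their 39 genes form 4 clusters whose windows share 24 different peaks. Against random runs of neighbouring genes of the same lengths, an alternative added after the data were seen, the adjusted p was 0.008 for the Notch list (1.82 times random) and 0.062 for the Hox list (1.99 times random). LGE regulators had 1.57 distal peaks per 100 kb, 0.938 times random (permutation test, adjusted p = 0.890), with 6 around Bcl11b, the same 4 around Dlx1 and around Dlx2, and none within 50 kb of the ends of Tle4. The ratio to random was 0.513 for D1 neuron markers, 1.15 for D2 neuron markers, 1.13 for spiny neuron and GABA markers, 1.12 for radial glia and progenitors, 1.02 for MGE and interneuron genes, 1.10 for dorsal cortical genes and 1.26 for the dorsal LGE and olfactory bulb. It was 1.52 for the oligodendrocyte lineage, 0.758 for vessels and microglia, 1.05 for TALE homeobox genes, 0.891 for retinoic acid, 0.946 for axon guidance, 0.537 for GABA and dopamine synapses, 0.988 for ribosomal proteins, 0.728 for keratins and 1.29 for liver, muscle and pancreas. None of these passed the one-sided test, which looks for more peaks only. D1 neuron markers, GABA and dopamine synapse genes and olfactory receptors lay below the central 95% of random lists, also when drawn as runs of neighbouring genes, a deficit that was not tested. That range is for each list on its own, without adjustment over the 20 lists. Keratins, in 4 clusters, lay below it only without the runs. Olfactory receptor genes had 0.607 times random for MEIS2 peaks and 1.87 times random for no-antibody peaks (permutation test, adjusted p = 0.002 for the latter, also against random runs of neighbouring genes). With the 5000 strongest peaks of each list, the MEIS2 ratio turned to 2.58 (permutation test, adjusted p = 0.002). The Notch result did not pass the permutation test with −log10 q of at least 5 (1.46 times random, adjusted p = 0.414) or with windows of 100 kb (1.5 times random, adjusted p = 0.053).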

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

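The random lists matched on gene length or local gene density, or drawn as runs of neighbouring genes, were alternatives chosen after the data were seen. The replicate overlap, the no-antibody overlap and, except among the strongest peaks, the odds ratio at gene ends kept their direction and significance under every alternative run; replicate 1 overlap ranged from 57.9% (50% reciprocal overlap) to 77.7% (5000 strongest peaks), and the odds ratio elsewhere from 7.23 to 38.6. The reproducible set held 73369 to 76287 peaks when one MEIS2 replicate was left out. With the 5000 strongest peaks of each list it held 3084, of which 83 lay at gene ends, and too few genes were hit for the gene-end list tests. The gene-end odds ratio was 1.55, and 0 lists were called higher and 0 lower at gene ends. The odds ratio of 12 lists above 1 in the main result fell to 0 (LGE regulators, D1 and D2 markers, radial glia, MGE, dorsal LGE, TALE, retinoic acid, Notch, axon guidance, Hox and ribosomal proteins). At this setting the distal ratios of Notch and Hox genes also fell to 0, and 1 list, olfactory receptors, was called for distal peaks (2.58). For these distal changes and the others named below the cause was not tested. With 50% reciprocal overlap, 0 lists were called higher at gene ends, and D2 markers (0.601), radial glia (0.984) and retinoic acid (0.935) moved below 1. With −log10 q of at least 5, 0 lists were called higher and 4 lower, with radial glia at 0.796, dorsal LGE at 0.493, retinoic acid at 0.341 and Hox genes at 0.443, and 1 list was called for distal peaks. At 2500 bp, 5 lists were called higher and 1 lower, with spiny neuron and GABA markers at 2.80, dorsal cortical genes at 2.59 and GABA and dopamine synapses at 1.08. A background of genes with a gene-end peak in any library leaves out genes without any gene-end peak, so its contrast is a different one and says little about the main calls. With it, 0 lists were called higher and 2 lower, olfactory receptors (0.151) and keratins (0.274), the latter not called in the main result. D1 markers gave no finite value. The odds ratios that crossed 1 were those of LGE regulators at 0.945, D2 markers at 0.735, dorsal LGE at 0.490, oligodendrocyte lineage and vessels and microglia both at 1.05, TALE at 0.462, axon guidance at 0.672 and Hox genes at 0.656. With one replicate left out, spiny neuron and GABA markers ranged from 0.808 to 1.09 and keratins from 0.841 to 1.49, above 1 without replicate 2, and with replicate 2 as the base list dorsal LGE was at 0.910. Ratios of distal peaks to random lists also crossed 1. With the 5000 strongest peaks this held for spiny neuron and GABA markers (0.493), dorsal cortical genes and the oligodendrocyte lineage (both 0), dorsal LGE (0.958), vessels and microglia (1.23), TALE (0.520), axon guidance (1.12), GABA and dopamine synapses (1.10) and liver, muscle and pancreas (0.813). It held for MGE and TALE genes with 50% reciprocal overlap (0.904 and 0.870) and with −log10 q of at least 5 (0.960 and 0.954). With one replicate left out, the ratio ranged from 0.929 to 1.13 for LGE regulators, 0.910 to 1.14 for vessels and microglia, 0.947 to 1.13 for MGE, 0.846 to 1.23 for retinoic acid, 0.970 to 1.18 for ribosomal proteins and 0.869 to 1.03 for keratins. Replicate 2 as the base list gave 1.05 for LGE regulators and 1.01 for ribosomal proteins, and keeping peaks with a no-antibody overlap gave 0.951 for MGE. Windows of 100 kb gave 0.955 for D2 markers, 0.955 for radial glia, 0.921 for MGE, 0.953 for dorsal cortical genes, 0.961 for dorsal LGE, 1.08 for retinoic acid and 1.12 for ribosomal proteins. Random lists matched on a gene-end peak gave 0.994 for MGE, those matched on gene length 0.988 for MGE and 1.11 for axon guidance, and those matched on local gene density 1.14 for LGE regulators and 1.18 for axon guidance. Apart from Notch, Hox, ribosomal proteins and olfactory receptors at the 5000 strongest peaks, none of the lists that changed side was called in the main result or after the change, in the test concerned. Windows of 100 kb left 1 list called for distal peaks, Hox, and random runs of neighbouring genes left 1, Notch. In all, 330 of 419 list values stayed on the same side of 1 and of the threshold and 70 crossed 1, and, counting both those that crossed and those that did not, 17 lost a call and 7 gained one, that background included. The alternatives for the 2 MEIS motif results were not run. No paired analysis was possible because the groups share only 1 replicate number. Lists of about 20 genes limit the gene-end test, which called 20.5% of simulated lists at 70% against 50%.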

Other observations

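The tests on the share of no-antibody peaks at gene ends were chosen after that share was seen, and the 3 patterns below were noticed in these data.

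The MEIS2 peaks that overlap a no-antibody peak, such as those inside Chl1 and at 12:3109793-3110159, include the highest in each library. Open chromatin tagged without an antibody is a possible source that these data do not settle. At gene ends lay 2.51% of no-antibody peaks, against 19.8% and 23.3% in the MEIS2 lists, so few of them could come from open gene ends. Open chromatin elsewhere was not measured. Regions where every library piles up also remain a candidate explanation. Across these 4472 peaks, pileups of replicate 1 and the no-antibody library had a Spearman correlation of 0.641, and those of the 2 MEIS2 replicates one of 0.964. The X chromosome held 9.99% of no-antibody peaks and 5.28% of reproducible MEIS2 peaks. Repeated or collapsed sequence was not tested, because no genome sequence was used here. No biological explanation was tested.

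The top decile of MEIS2 peaks by fold enrichment, clear of no-antibody peaks, lay at gene ends less often than weaker peaks did. A technical explanation is that the local expected pileup is higher near gene ends, which lowers the fold enrichment there. Its median was 1.29 tags for gene-end peaks of replicate 1 and 0.963 elsewhere, so the difference exists over all these peaks. Within the top decile by fold enrichment it went the other way (1.07 and 1.34). The explanation is argued against as the cause, since ranking by pileup alone left 10.8% of the top decile at gene ends. The eighth decile had 38.3% by fold enrichment and 42.5% by pileup. Of that top decile by pileup, 57.5% lay between genes and 9.75% on X or Y, against 5.75% on X or Y for all these peaks. Strong binding of MEIS2 at sites far from genes, and signal in repeats too weak in the control library to be called, both stay open, since the motif was not searched.

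Reproducible MEIS2 peaks at gene ends were found at genes of several lists besides LGE regulators. Untargeted cutting strong enough to be called was not concentrated at gene ends: no-antibody peaks were 0.419 times as frequent there as after shifting. Weaker untargeted signal at gene ends leaves no peak and was not measured, so it stays open. Active promoters of any kind may account for part of the signal. Ribosomal protein genes had a gene-end peak in 69.2% of cases, and so did LGE regulators, while at 2.5 kb the odds ratio of LGE regulators was 4.96, that of MGE and interneuron genes 8.41 and that of ribosomal proteins 2.16. In the 1 kb result, olfactory receptors and liver, muscle and pancreas genes rarely had one, while 25 of 39 Hox genes and 21 of 49 keratins did. The activity of these genes in the tissue was not measured here. Whether MEIS2 itself or an off-target preference for active promoters brings the signal there was not tested, since no library with an unrelated antibody was analysed here. The difference between LGE regulators and ribosomal protein genes was not tested.

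A further hypothesis was that distal MEIS2 peaks are denser around LGE regulators than around regulators of neighbouring regions. The mean was 1.57 ± 1.15 (SD, n = 26) distal peaks per 100 kb around LGE regulators and 1.78 ± 1.18 (SD, n = 29) around MGE and dorsal cortical genes. The difference of -0.211 (95% bootstrap interval -0.810 to 0.405, two-sided permutation p = 0.508) does not show denser peaks around LGE regulators. A difference above 0.405 in their favour lies outside the interval. The lists are small, and nearest genes need not be the targets of distal peaks.

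Short and non-coding genes also carried MEIS2 peaks at their ends. Reproducible peaks lay within 1 kb of an end in 18.4% of 12727 lncRNA genes, 16.2% of 408 tRNA genes and 13.4% of 1228 miRNA genes, against 52.4% of protein-coding genes. Among genes more than 2 kb from any protein-coding gene the shares were 9.25%, 9.97% and 7.29%. There, pseudogenes were at 9.47%, transcribed pseudogenes at 20.9%, miscellaneous RNA genes at 21.1%, and snoRNA and snRNA genes at 4.01% and 3.96%. These classes were not tested against each other or against shifted peaks. In genes as short as those of tRNA (median 72 bp, against 17169 bp for protein-coding genes) the windows at the ends overlap, which leaves less room for a peak.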
